A study of Mus musculus with 4 samples.

How the data were processed

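RNA was measured by sequencing in 4 libraries of E14 mouse embryonic stem cells, 2 sampled at 0 h and 2 after 24 h with 1 µM ATRA. Groups and replicate numbers were taken from the sample titles. The titles and the treatment protocol give a micromolar concentration, while a treatment label on the ATRA samples gives a millimolar unit, and the titles were followed. Per the labels' protocols, RNA was extracted with Trizol and libraries followed the standard Illumina procedure. The protocols also describe neural differentiation in embryoid bodies, but the labels call all 4 samples embryonic stem cells. They name dimethyl sulfoxide as the vehicle and do not say whether the 0 h cells received it.

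The authors deposited a table per library of whole-number read counts per gene symbol, not normalized. The submitters' processing notes name TopHat2 2.0.7, Cufflinks 2.0.2, HTSeq 0.6.0 and Cuffdiff 2.0.2 and the genome build mm10, with no role or order. The gene annotation and the strand setting of the counting are not given in the sources used here, so reads of a gene and of an overlapping antisense gene could not be told apart. Each table held 23420 genes and 5 summary lines. The summary lines were left out of library sizes and tests. Reads in no annotated gene made up 63.4% and 63.9% of all counted reads in the control libraries and 64.7% and 66.2% in the ATRA libraries, and ambiguous reads 0.254%, 0.239%, 0.190% and 0.158%. Counts in genes ranged from 11086233 to 31005634 per library. A count of 3 in a library, taken as the upper limit that a count of 0 allows, stands for 0.0968 to 0.271 CPM. Such floors, and the exact counting intervals at 95% given for genes with 1 to 3 counts in a group, cover counting error only. Spearman's rho of the log counts across genes was 0.995 between the control libraries and 0.950 between the ATRA libraries.

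Symbols were matched to GENCODE M21 (GRCm38, the assembly that mm10 names), 21777 directly and 1278 through an older symbol, and 365 had no match. Coordinates are GENCODE's, since the count tables hold none. GC content and length were taken from the longest protein-coding transcript of each gene where there was one, and 14146 of the tested genes (99.2%) had a value.

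Counts were analysed with edgeR 4.0.16 in R 4.3.3: the default expression filter by group, TMM factors, a robust quasi-likelihood fit and its F test of ATRA against control, with Benjamini-Hochberg adjustment and a threshold of 0.05. No covariate was used. CPM values use TMM-scaled library sizes. Fold changes are on the log2 scale, ATRA over control, and each standard error (SE) is the size of the fold change divided by the square root of its F statistic. A set of 28 gene lists was fixed before the data were examined. Lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with its preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation, under which 0 lists passed. The preset correlation gave 13 lists past the threshold, and fry, which asks whether a list's own genes move one way, gave 12. HOX genes of paralog groups 1 to 5 and 6 to 13 were compared by a permutation test of the difference of medians (100000 resamples, two-sided). Genes were named by a rule also fixed then: the 10 largest rises and falls among called genes with non-overlapping libraries and a mean of at least 5 CPM in the higher group; in each list the 3 called members with the smallest p, or the most abundant member where none was called; 16 genes chosen in advance (among them the RAR and RXR genes, Cyp26a1, Hoxb1, Pou5f1, Nanog, Sox2, Zfp42, Prmt1, Prmt8 and Stra8); and the 3 most abundant called genes in each direction. Some genes named by this rule are not reported here, singly or in the figures, and stay in the counts and medians. Other list members given as examples after GC correction were chosen after their values were seen.

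A correction for GC content was added after seeing the data. For each library, the deviation of each gene's log2 CPM (prior count 2) from its mean over libraries was fitted against transcript GC content with a natural spline of 5 degrees of freedom by robust regression (MASS 7.3.60.0.1), using genes with a mean log2 CPM above 1, and the fitted values entered edgeR as offsets. GC values beyond the outermost percentiles were held at them, and genes with no GC value were left uncorrected. The correction takes out any GC-related difference between libraries, whether technical or caused by the treatment. Its median log2 fold change over all genes was 0.01, against −0.02 without it.

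The scripts were tested on simulated counts with the control means, the real library sizes and the spread between replicates of the GC-corrected fit. The simulated counts held 200 changed genes, for control against ATRA. Without a GC trend (13905 genes), the uncorrected fit recovered 56% of genes changed 2-fold and 92% of genes changed 4-fold, with 16 false calls among 164, and the corrected fit 55% and 92%, with 14 among 161. With the GC trend of the real libraries added (13917 genes, 198 of them changed), the uncorrected fit made 2119 calls of which 94.3% were false, and recovered 45% and 76.5%. The corrected fit made 162 calls, 15 of them false, and recovered 53% and 95.9%. The added trend was the spline that the correction itself fits, so the advantage of the corrected fit was built in. The simulated trend was also stronger, with a Spearman rho of fold change and GC content of −0.94, against −0.75 in the data. The share of false calls cannot be carried over to the 161 uncorrected calls of the data.

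Settings varied by plan were DESeq2 size factors, library size alone, DESeq2 1.42.0, limma-voom, a non-robust fit, the older quasi-likelihood method, no count filter, a filter of 5 CPM in 2 libraries, a threshold of 0.01, a test against a 2-fold change, the replicate number as a block, and each library left out in turn. Added after seeing the data were the GC correction, alone, with transcript length and with the block, and the planned variations within it. Multigene families whose reads can be shared between copies, such as Zscan4 and Usp17l, are uncertain gene by gene. Counting intervals, rank correlations and figures used scipy 1.17.1, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.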

Results

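The data are RNA sequencing counts from E14 mouse embryonic stem cells, a feeder-free line kept undifferentiated with leukemia inhibitory factor (LIF). Cells were sampled at 0 h and after 24 h with 1 µM all-trans retinoic acid (ATRA), the ligand of the retinoic acid receptors, which bind DNA together with retinoid X receptors (RXR). Each group had 2 libraries. Counts assigned to genes came to 31005634 and 21484812 in control replicates 1 and 2, and to 13337972 and 11086233 in ATRA replicates 1 and 2, so the ATRA group was measured at the lower depth. At these depths 3 counts correspond to between 0.0968 and 0.271 CPM (counts scaled to library size), and 17822, 17339, 17098 and 16381 genes had at least 1 count. The series title places the experiment in work on RXR-mediated neurogenesis. The comparison asks which transcripts differ between ATRA-treated and 0 h stem cells. The control is the 0 h sample, so ATRA and 24 h of culture vary together. No label says that the replicates came from separate cultures, and p-values then measure only the spread between these libraries, which may be technical. Replicates of both groups differed by more than sampling noise, with a chi-square per degree of freedom of 10.1 for the controls and 82.4 for the ATRA libraries.

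After 24 h of ATRA, 12 of 13 tested HOX genes of paralog groups 1 to 5 rose, several from near-absence, with a median log2 fold change of 5.53 over the 13. The receptor gene Rarb, 5 of 12 tested genes that handle retinoids and 5 of 12 tested HOX genes of groups 6 to 13 also rose. The naive pluripotency genes Zfp42 and Esrrb, the formative epiblast genes Otx2, Foxd3 and Dnmt3b and the primitive streak genes T, Evx1 and Fgf8 fell. Of 14256 genes tested, 161 changed, 103 of them higher and 58 lower with ATRA (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p under 0.05, n = 2 against 2). All 161 differed at least 2-fold, and 5941 genes had an unadjusted p under 0.05. With so many small p over all genes, counts adjusted over a list alone, given below, do not by themselves set a list apart. The share of higher genes among the calls was 64.0%, against 38.5% of 603 calls when DESeq2 size factors replaced the TMM factors. With a single library left out, the count was 125 without control replicate 1 (51 higher), 662 without control replicate 2, 10289 without ATRA replicate 1 and 7302 without ATRA replicate 2, the lone library being assumed to vary like the other group.

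The ATRA libraries also differed from each other along transcript GC content. The median log2 ratio of ATRA replicate 2 to ATRA replicate 1 was 0.85 in the GC decile with the lowest content and −1.31 in the highest. The same ratio between the control replicates was −0.01 and −0.31. Fold changes between the groups followed GC content with a Spearman rho of −0.75 across 14146 genes, which are not independent replicates. The genes called lower had a median GC content of 56.5% and those called higher 48.6%, against 50.2% over all genes tested. A GC correction per library, chosen after seeing the data, brought rho to −0.00108 and lowered the biological coefficient of variation from 28.3% to 15.4%. Both follow from how the correction is fitted, and neither shows that it removes only bias. With the correction, 2312 genes changed, 1216 higher and 1096 lower, and 1352 of them at least 2-fold. Of the 161 genes, 103 rose and 47 fell in both fits, and 11 lost their call. The GC-corrected count was 35 without control replicate 1, 25 without control replicate 2, 6699 without ATRA replicate 1 and 4957 without ATRA replicate 2. GC-corrected values are therefore given beside most uncorrected ones. Counts of list members called with a library left out, given below, are to be read against the counts over all genes above.

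**Figure D1:**
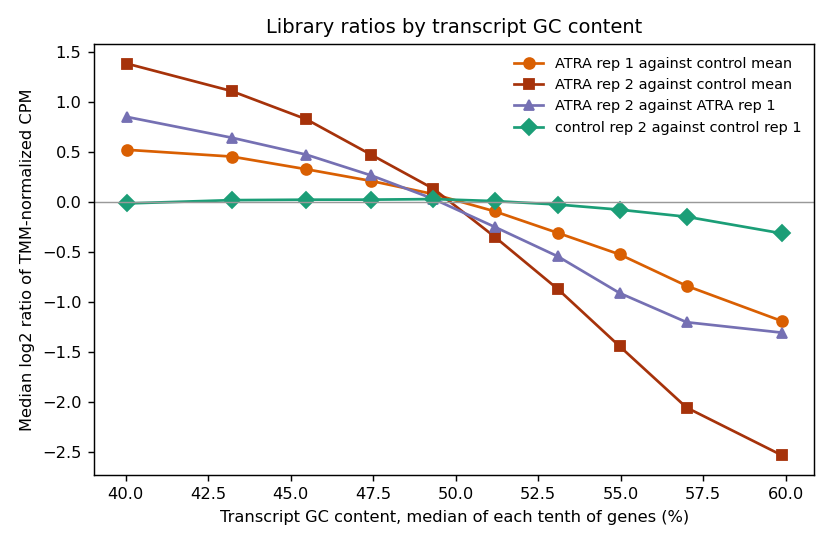
Median log2 ratio of TMM-normalized CPM (y axis) against the median transcript GC content in percent of each decile of genes (x axis), for each ATRA library against the control mean and for the replicates of each group against each other. ATRA replicate 2 against ATRA replicate 1 runs from 0.85 to −1.31, and control replicate 2 against control replicate 1 from −0.01 to −0.31.

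Rarb, the gene of retinoic acid receptor beta and itself a direct retinoic acid target, had the largest uncorrected rise of the genes named by the preset rule (after GC correction Hoxb3, at 7.85, and Hoxb2, at 7.72, were above it). It lies on chromosome 14 from 16430839 to 16819156, minus strand (GENCODE M21, GRCm38). It went from 0.174 ± 0.0688 CPM in the controls to 38.7 ± 6.71 CPM with ATRA (mean ± SD, n = 2 each), a log2 fold change of 7.80 ± 0.49 (SE) with an edgeR adjusted p of 0.0124, and of 7.53 after GC correction. Stra8, a retinoic acid-induced gatekeeper of meiosis on chromosome 6 from 34920163 to 34939344, plus strand, rose from 2.17 ± 0.402 to 342 ± 47.4 CPM, by 7.31 ± 0.37 on the log2 scale (edgeR adjusted p = 0.0124), and by 7.47 after GC correction. Of the 10 largest rises, 6 more were HOX genes (Hoxb1, Hoxb2, Hoxb3, Hoxb4, Hoxb5 and Hoxa5). The chemokine precursor gene Ppbp (6.15, or 5.29 after GC correction) and the kappa-casein gene Csn3 (5.64, or 4.56) completed the group. Without control replicate 1 the values of Hoxb3, Ppbp and Hoxb4 were 8.42, 7.66 and 7.19, and without ATRA replicate 1 that of Hoxb5 was 5.85. In the uncorrected fit the calls of these 10 genes held with each single library left out. In the GC-corrected fit not all of them held without control replicate 2.

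Among the largest falls, Ly6g6e had 298 counts in the controls and 0 with ATRA, which makes it at least 43.6-fold lower against a floor of 3 counts over the group. The keratin gene Krt17 had 409 counts against 3 and was 59.8-fold lower, with a 95% counting interval from 20.3 to 291 (fitted log2 fold change −5.82, or −4.37 after GC correction). These bounds and intervals cover counting error only. Otx2, a homeobox gene of the formative epiblast and anterior brain on chromosome 14 from 48657677 to 48673819, minus strand, went from 28.9 ± 2.09 to 1.22 ± 0.321 CPM. It fell by 4.59 on the log2 scale (SE 0.41, edgeR adjusted p = 0.0196), and by 4.97 after GC correction. Tdh, which encodes the threonine dehydrogenase that mouse stem cells depend on, fell from 359 ± 6.91 to 19.8 ± 8.64 CPM, with a log2 fold change of −4.17 (−3.60 after GC correction). Enpp2, the gene of the enzyme autotaxin, was at −4.22 and −4.83, and Tgm3 at −4.47 in both fits (−5.13 without ATRA replicate 2). Among genes of high GC content the falls were smaller once corrected, from −5.40 to −3.57 for Foxd3, from −4.55 to −2.65 for Tfeb and from −4.05 to −2.52 for Krt42. The uncorrected values of Tfeb and Krt42 were −6.21 and −5.18 without ATRA replicate 1, and without ATRA replicate 2 that of Foxd3 was −4.62. The fall of 1700097N02Rik, at −4.23, was −2.82 with an edgeR adjusted p of 0.0596 after correction. The most abundant genes that rose were the cell-surface receptor gene Prtg (log2 fold change 2.36, or 1.98 after GC correction), the imprinted gene Mest (2.57, or 2.25) and Stra8. The most abundant that fell were the DNA methyltransferase gene Dnmt3b (−2.11, or −1.48), Zfp42 (−1.94, or −2.36) and the kinase gene Sgk1 (−1.87, or −2.04). Prtg, Mest, Zfp42 and Sgk1 kept their calls after GC correction and lost them without either control replicate, with edgeR adjusted p from 0.0537 to 0.162. Dnmt3b lost its call without control replicate 1 (edgeR adjusted p = 0.126).

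Of 12 tested genes that handle retinoids, Cyp26a1, Cyp26b1, Crabp2, Dhrs3 and Stra6 rose and 0 fell, or 5 rose and 1 fell adjusted over the list alone. Cyp26a1, which encodes the main retinoic acid-degrading hydroxylase and lies on chromosome 19 from 37697798 to 37701536, plus strand, rose from 8.65 ± 0.618 to 267 ± 91.9 CPM. Its log2 fold change was 4.94 ± 0.39 (5.83 after GC correction). Cyp26b1, a related hydroxylase, rose by 4.24 (5.53 after GC correction), the cellular retinoic acid-binding protein gene Crabp2 by 3.52 (3.60), and the retinol transporter gene Stra6 by 4.98 (6.11). The list stood above other genes (camera adjusted p = 2.74e-04), with an adjusted p = 0.244 with an estimated correlation. After GC correction 5 rose and Rdh11 fell. With single libraries left out, between 3 genes (control replicate 1) and 6 (either ATRA replicate) rose, and between 1 and 6 in the GC-corrected fit. Cyp26b1 lost its call without control replicate 1 (edgeR adjusted p = 0.0667).

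Among the 6 RAR and RXR genes, Rarb alone changed (1 rose, 0 fell, and 1 rose and 3 fell adjusted over the list alone). Rara (log2 fold change −1.25), Rarg (−1.72), Rxra (−1.13) and Rxrb (−1.78) did not pass the test, and after GC correction they were at 0.34, −0.05, 0.18 and 0.02. Rxrg, at low levels (2.59 ± 0.455 CPM in the controls and 0.277 ± 0.192 with ATRA), was at −3.32 with an edgeR adjusted p of 0.0578, and at −2.47 with 0.0597 after correction. It passed without control replicate 2 (edgeR adjusted p = 0.0243). The list's shift turned with the correction, from downward with a camera adjusted p of 0.613 to upward with 0.0199, where the adjusted p = 0.294 with an estimated correlation. Uncorrected, the list's median was −1.48 and its mean −0.23; corrected, they were 0.10 and 0.93. Without ATRA replicate 1, 5 of the 6 genes fell uncorrected and 0 after correction, and without ATRA replicate 2 the counts were 4 and 2.

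Of 19 other known retinoic acid-responsive genes, 9 rose and 1 fell, or 12 and 2 adjusted over the list alone. The second of those falls was that of Stra13 (−1.55), a symbol with no match in GENCODE M21, so its place in the list is uncertain. The homeobox cofactor genes Meis2 (4.90 ± 0.35) and Meis1 (4.11) were among them, with the myelin gene Pmp22 (3.40 ± 0.28) and the nuclear receptor corepressor gene Nrip1 (2.88 ± 0.30). After GC correction these 4 stood at 4.56, 3.28, 3.23 and 2.20. The immediate early gene Egr1, the member that was lower (−2.36), was at −0.79 with an edgeR adjusted p of 0.183 after correction. The list's camera adjusted p was 3.42e-14, and the adjusted p = 0.185 with an estimated correlation. In the GC-corrected fit 13 rose and 0 fell. Without control replicate 1, 7 rose, and without ATRA replicate 1 or 2, 14 and 14 rose and 4 and 3 fell, while the GC-corrected fit without either control gave 6.

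HOX cluster genes of paralog groups 1 to 5 rose in 12 of the 13 tested, and 13 adjusted over the list alone. Their median log2 fold change was 5.53 (6.64 after GC correction, where all 13 rose). Hoxb1, on chromosome 11 from 96365752 to 96368256, plus strand, went from 0.630 ± 0.261 to 72.9 ± 14.2 CPM, a log2 fold change of 6.80 ± 0.46 (edgeR adjusted p = 0.0158, and 7.52 after GC correction). Hoxc5 had 2 counts in the controls and 116 with ATRA, 132-fold higher with a counting interval from 35.8 to 1105 (fitted log2 fold change 6.79, or 6.91 after GC correction). Hoxd3, which had too few counts for the test, had 0 against 18 counts and was at least 13.7-fold higher. Of 12 tested genes of groups 6 to 13, 5 rose and 0 fell (8 and 0 adjusted over the list alone), with a median of 2.99 (3.55 after GC correction, where 9 rose). These groups have 24 genes in the data, and those not tested had too few counts. With no count filter the median was 1.81 over 23 genes of groups 6 to 13, and 5.47 over 15 genes of groups 1 to 5. Hoxb7 rose by 5.19 (5.40 after GC correction), Hoxb6 by 5.04 (corrected value in the figure) and Hoxb9 by 2.95 (3.46), while Hoxc13, chosen after its value was seen, was at −0.12 (0.67) and did not pass. The camera adjusted p was 1.96e-37 for groups 1 to 5, where the adjusted p = 0.145 with an estimated correlation, and 2.88e-10 for groups 6 to 13, where it was 0.185. The medians differed by 2.54 (two-sided permutation test across genes with 100000 resamples, p = 0.00045), and by 3.09 after GC correction. Genes are not independent replicates. With groups 1 to 4 set against 5 to 13 the difference was 1.65 (p = 0.055), and among the 15 genes with at least 5 CPM in 2 libraries it was 0.58 (p = 0.422, permutation tests). After GC correction, without control replicate 1 or 2, 6 and 5 genes of groups 1 to 5 rose and 3 and 2 of groups 6 to 13, and without either ATRA replicate at least 8 of groups 6 to 13 rose in both fits.

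**Figure D2:**
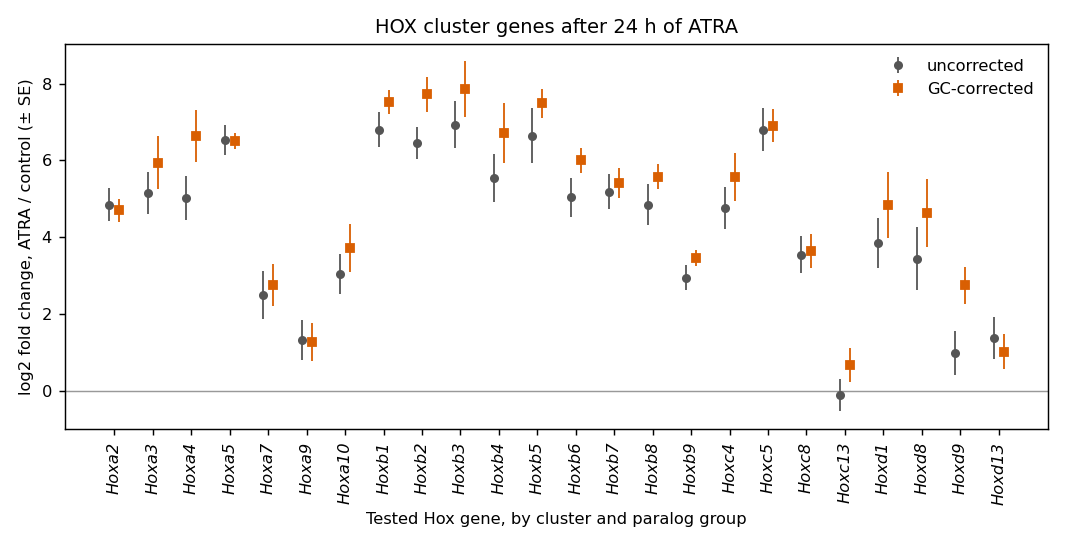
Log2 fold change with its standard error (y axis) of tested HOX genes, ordered by cluster and paralog group (x axis), from the uncorrected fit (circles) and the GC-corrected fit (squares), 2 libraries per group. The medians of groups 1 to 5 and of groups 6 to 13 are 5.53 and 2.99 uncorrected, and 6.64 and 3.55 GC-corrected.

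Of 15 tested naive pluripotency genes, Zfp42, Esrrb and Klf2 fell and 0 rose, and 13 fell adjusted over the list alone. Zfp42 (Rex1), on chromosome 8 from 43295063 to 43306980, minus strand, went from 568 ± 8.89 to 148 ± 4.2 CPM, a log2 fold change of −1.94 ± 0.26 (−2.36 after GC correction). The orphan receptor gene Esrrb was at −2.63 (−1.68). Klf2, whose GC content is 61.6%, was at −2.08 uncorrected and at 0.13 with an edgeR adjusted p of 0.858 after correction. With the GC correction, 11 genes fell, and Tbx3 rose (1.39, against 0.49 uncorrected with an edgeR adjusted p of 0.220). Nanog was then among those that fell, at −1.16 (edgeR adjusted p = 0.0253), against −0.67 (0.108) uncorrected. The list lay below other genes (camera adjusted p = 2.82e-06), with an adjusted p = 0.218 with an estimated correlation. Between 1 and 2 genes fell without a control library and 13 without either ATRA library, and in the GC-corrected fit 1 and at least 11. Zfp42 lost its call without either control replicate, with edgeR adjusted p of 0.160 and 0.0835.

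Among 12 genes shared by naive and primed cells, Utf1 fell (−3.88, or −1.74 after GC correction) and 0 rose, or 1 rose and 5 fell adjusted over the list alone, with a camera adjusted p of 0.169 (0.00746 without ATRA replicate 2). After correction 2 rose and 4 fell, and the camera adjusted p was 0.0331, or 0.298 with an estimated correlation. Corrected and without either control replicate, 0 of these 12 passed. Pou5f1 (Oct4), on chromosome 17 from 35506018 to 35510772, plus strand, had 1265 ± 19.6 CPM in the controls and 207 ± 143 with ATRA. Its 2 ATRA libraries were at 307 and 106 CPM, and its log2 fold change was −2.61 ± 0.53 with an edgeR adjusted p of 0.0621. It passed after GC correction at −1.27 ± 0.14 (edgeR adjusted p = 0.0115). Its uncorrected value was −3.60 without ATRA replicate 1 and −2.03 without ATRA replicate 2. Sox2 did not pass, at −0.13 and −0.02 in the 2 fits. It was at 0.28 (edgeR adjusted p = 0.0138) without ATRA replicate 1 and at −0.71 (0.000286) without ATRA replicate 2. Of 12 formative or primed epiblast genes, Otx2, Foxd3 and Dnmt3b fell and 0 rose (1 rose and 6 fell adjusted over the list alone). The list's camera adjusted p was 0.00126, and the adjusted p = 0.330 with an estimated correlation and 0.119 without ATRA replicate 1. Corrected, 5 fell, Fgf5 (−2.46) among them, and the transcription factor gene Sall2 rose (2.07). Without ATRA replicate 1 or 2, 8 and 8 of them fell and 2 and 1 rose uncorrected, 7 and 7 fell and 4 and 1 rose corrected, and corrected without either control 1 fell.

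**Figure D3:**
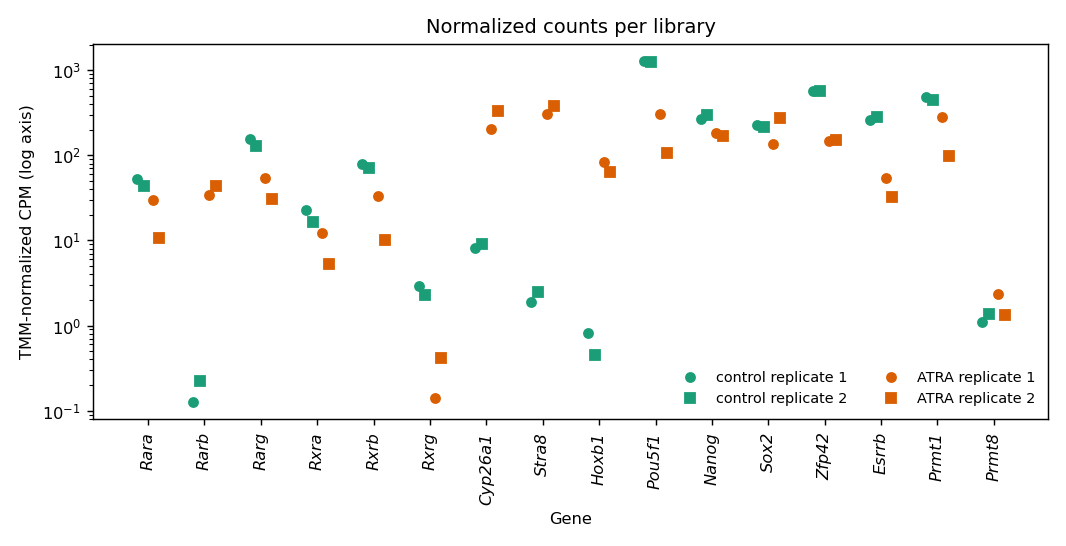
TMM-normalized CPM on a log axis (y axis) of receptor, retinoid target, pluripotency and arginine methyltransferase genes (x axis), with a point for each of the 4 libraries (circles for replicate 1, squares for replicate 2, green for control and orange for ATRA). Stra8 lies near 2.17 CPM in the controls and near 342 with ATRA, while the ATRA libraries of Pou5f1 lie apart at 307 and 106 CPM.

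Of 15 primitive streak and early mesoderm genes tested, T, Evx1 and Fgf8 fell and 0 rose (1 rose and 7 fell adjusted over the list alone). T (brachyury), on chromosome 17 from 8434423 to 8442496, plus strand, went from 134 ± 18.0 to 9.96 ± 2.69 CPM, a log2 fold change of −3.76 ± 0.34 (edgeR adjusted p = 0.0219), and of −3.33 after GC correction. Evx1 had 163 counts in the controls and 1 with ATRA, 71.5-fold lower with a counting interval from 12.7 to 2841 (fitted log2 fold change −5.94, or −4.32 after GC correction). Fgf8 was at −3.84 (−5.19 without ATRA replicate 1, and −1.99 after correction). Msgn1, with 91 against 0 counts, was at least 13.3-fold lower and had an edgeR adjusted p of 0.0570, or 0.0421 after GC correction. As a set these genes had a camera adjusted p of 0.00126, of 0.248 with an estimated correlation, and of 0.135 without ATRA replicate 1. After GC correction 6 fell and Meox1 rose, with a camera adjusted p of 0.167. Without either ATRA library 7 fell and 1 rose uncorrected, and corrected without either control 0 fell.

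The neural progenitor gene Sox1, which marks early neuroectoderm and lies on chromosome 8 from 12395295 to 12400126, plus strand, rose from 1.58 ± 0.0280 to 27.3 ± 4.89 CPM. Its log2 fold change was 4.10 ± 0.37 (edgeR adjusted p = 0.0196), and 5.69 after GC correction. It was the only call among 14 neural progenitor genes (3 rose and 1 fell adjusted over the list alone), and the camera adjusted p was 0.269. In the GC-corrected fit 6 rose, with Pax6 (1.36) and Sox3 (1.78) among them, and Neurod1 fell (−1.76). Sox3, whose GC content is 66.4%, was at −0.19 uncorrected (edgeR adjusted p = 0.785), so its rise rests on the correction. It had 60 and 16 counts in ATRA replicates 1 and 2. After GC correction the progenitor list had a camera adjusted p of 0.0159, and an adjusted p = 0.294 with an estimated correlation. Of 16 neuronal genes, Dcx rose (3.64, or 2.69 after GC correction) and Tubb3 fell (−2.80), or 2 rose and 3 fell adjusted over the list alone, with a camera adjusted p of 0.453. Tubb3 was at −3.43 without ATRA replicate 1, and at −1.32 after GC correction, where 2 genes rose and 3 fell. Dcx lost its call without control replicate 1 (edgeR adjusted p = 0.117). Of 9 neural crest genes, Msx1 rose (3.30, or 4.98 after correction) and 0 fell, or 2 rose and 1 fell adjusted over the list alone. The camera adjusted p was 0.0375, and the adjusted p = 0.330 with an estimated correlation, 0.168 without control replicate 2 and 0.430 without ATRA replicate 1. The antisense gene of Msx1, Msx1as, chosen after its value was seen, rose by 3.32 as well, and the strand setting of the counting, which decides how reads of such a pair are assigned, is not stated. Msx1 lost its call without control replicate 1 (edgeR adjusted p = 0.0732). Corrected, 3 neural crest genes rose, and without either control replicate 0 genes of these 3 lists passed. Uncorrected and without ATRA replicate 1 or 2, 3 and 3 progenitor genes rose and 2 and 2 fell, 3 and 3 neural crest genes rose and 1 and 1 fell, and 3 and 2 neuronal genes rose and 7 and 6 fell.

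Among 17 extraembryonic endoderm genes, 1 rose and 0 fell, or 6 rose and 4 fell adjusted over the list alone, with a camera adjusted p of 0.442. After GC correction, 7 rose, including Gata6 (4.44) and Gata4 (1.82), and 2 fell. Uncorrected, Gata6 was at 2.87 (edgeR adjusted p = 0.0649) and Gata4 at 0.50 (0.453), so these calls rest on the correction. Their counts were low, 21 and 10 in the controls and 33 and 60 with ATRA for Gata6, and 61 and 46 against 55 and 15 for Gata4. The list's camera adjusted p after GC correction was 0.0320, and the adjusted p = 0.336 with an estimated correlation. Without ATRA replicate 1 or 2 the uncorrected fit had 5 and 8 that rose and 7 that fell. Of 6 definitive endoderm genes, Foxa1 rose (4.08 ± 0.53, 3.45 without ATRA replicate 2 and 5.09 after GC correction) and 0 fell, 1 in each direction adjusted over the list alone, with a camera adjusted p of 0.652, and 1 rose and 1 fell after GC correction. None of 12 trophoblast genes passed by edgeR, or 3 rose and 3 fell adjusted over the list alone, with a camera adjusted p of 0.453 and Krt18 at −1.31, or −0.16 after GC correction. With the GC correction, 3 rose and 2 fell, among them Cdx2 (2.59, against 0.98 uncorrected) and Krt19 (−1.49, against −2.84 uncorrected). Of 13 fibroblast genes, 0 passed, or 1 rose and 2 fell adjusted over the list alone, with a camera adjusted p of 0.652. Tagln, the most abundant, had 403 ± 13.7 CPM in the controls and 253 ± 47.5 with ATRA (log2 fold change −0.67, or −0.23 after GC correction). After GC correction 3 fibroblast genes rose (Dcn, Pdgfrb and Fbn1). Without ATRA replicate 1 or 2, 2 and 2 of these rose and 5 and 4 fell uncorrected, and without either control 0 genes of these 4 lists passed after correction.

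Of 15 tested genes of the rare 2-cell-like state of stem cell cultures, Zscan4c (2.31 ± 0.34) and Zscan4f (2.34 ± 0.34) rose and 0 fell, and 13 rose adjusted over the list alone. As a set these genes had a camera adjusted p of 6.37e-09, and the adjusted p = 0.197 with an estimated correlation. Zscan4 genes are near-identical copies, so single members are uncertain. Camera with its preset correlation took these copies, and those of Usp17l, almost as independent genes, so its p overstates the evidence. The summed level of Zscan4 over 6 copies went from 108 ± 10.2 to 552 ± 198 CPM, 5.10 times the control mean. Corrected, all 6 copies rose, by 1.43 to 1.68 (Zscan4c by 1.46 and Zscan4f by 1.63), and 8 of the 15 genes passed. Without either control library 0 genes of the list passed in either fit, and without ATRA replicate 1 or 2, 11 and 11 passed uncorrected and 9 and 10 corrected. Of 14 germline and meiosis genes, Stra8 rose and 0 fell, and 11 rose adjusted over the list alone, with a camera adjusted p of 3.26e-07 and an adjusted p = 0.368 with an estimated correlation. Their median GC content was 40.9%, and their median log2 fold change was 1.54 uncorrected and 0.67 corrected. After correction 4 rose: Stra8, Rec8 (1.83), Tex11 (1.35) and Dazl (0.77). Without ATRA replicate 1 or 2, 12 and 9 rose uncorrected and 10 and 6 corrected, while without either control replicate 1 rose in both fits.

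No label says whether LIF was present during the 24 h with ATRA, so a change of LIF and ATRA itself are not separated for its pathway. Of 11 tested genes of the LIF and STAT3 pathway, which sustains self-renewal, the feedback inhibitor gene Socs3 fell (−3.07, or −3.69 without ATRA replicate 1 and −1.47 after GC correction) and 0 rose, and 6 fell adjusted over the list alone. The camera adjusted p was 0.00222, and the adjusted p = 0.248 with an estimated correlation. In the GC-corrected fit 5 fell, among them Lifr (−1.47) and Stat3 (−0.93), and Pim1 rose (1.63). The uncorrected fit had 1, 4, 7 and 8 that fell without control replicate 1, control replicate 2, ATRA replicate 1 and ATRA replicate 2, and the corrected fit 0 without either control replicate. Of 15 FGF and ERK targets, Egr1 fell and 0 rose, or 2 rose and 9 fell adjusted over the list alone. The list's camera adjusted p was 0.00469, and the adjusted p = 0.248 with an estimated correlation and 0.155 without ATRA replicate 1. With Egr1 no longer called, 3 rose and 4 fell in the GC-corrected fit, with Dusp6 (1.23) higher and Spry4 (−1.37) lower, and the camera adjusted p was 0.0827. Of 14 Wnt targets, Notum (−4.01, with −5.30 without ATRA replicate 1 and −2.46 after GC correction) and Sp5 (−2.41) fell and 0 rose, or 4 rose and 6 fell adjusted over the list alone, with a camera adjusted p of 0.403. Sp5 was at −0.32 with an edgeR adjusted p of 0.527 after GC correction, where 3 rose (Cdx1, Cdx2 and Cdx4) and 3 fell. Without either ATRA replicate 4 Wnt targets rose and at least 7 fell, and 3 FGF and ERK targets rose and at least 10 fell. Corrected and without either control replicate, 1 Wnt target rose and 0 FGF and ERK targets passed.

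Of 10 Nodal pathway genes, 0 passed by edgeR, or 1 rose and 5 fell adjusted over the list alone, with a camera adjusted p of 0.456. Skil was at 1.26, or 0.32 after GC correction, and did not pass. After GC correction Lefty1 rose (2.13), and Tdgf1 and Gdf3 fell. None of 13 liver X receptor genes and targets passed by edgeR, or 2 rose and 7 fell adjusted over the list alone. Their camera adjusted p was 0.0464, and the adjusted p = 0.385 with an estimated correlation and 0.119 without ATRA replicate 1. After GC correction, Scd1 rose (0.55) and 6 fell, among them Abca1 (−1.28) and Apoe (−1.15), with a camera adjusted p of 0.0555. Of 17 nuclear receptor coregulator and arginine methyltransferase genes, Nrip1 rose and 0 fell, or 1 in each direction adjusted over the list alone, with a camera adjusted p of 0.963. Prmt1 (−1.30, or −0.49) did not pass in either fit. Prmt8 was at 0.61 with an edgeR adjusted p of 0.323, and rose after GC correction (1.59, edgeR adjusted p = 0.0421). Its counts were low, 35 and 31 in the controls and 33 and 13 with ATRA. Uncorrected, its libraries overlapped, at 1.10 and 1.38 CPM in the controls and 2.33 and 1.34 CPM with ATRA. Nrip1 lost its call without control replicate 1 (edgeR adjusted p = 0.0747). Of 16 hypoxia and glycolysis genes, 0 passed by edgeR, or 4 fell adjusted over the list alone, with a camera adjusted p of 0.101 (0.0246 and 0.0424 without ATRA replicate 1 and 2). The glucose transporter gene Slc2a3 was at 0.20, or 0.13 after GC correction. After correction 1 rose and 4 fell, Pdk1 (−1.44) and Ndrg1 (−1.67) among them, and the camera adjusted p was 0.0470, with an adjusted p = 0.336 with an estimated correlation. Eno1 in that list shares reads with the near-identical copy Gm5506 and is uncertain. Without ATRA replicate 1 or 2, 3 and 1 Nodal pathway genes rose and 6 and 6 fell, 3 and 1 liver X receptor genes and targets rose and 9 and 7 fell, 6 and 3 coregulator genes rose and 7 and 6 fell, and 3 and 3 hypoxia genes rose and 10 and 7 fell. After correction 0 genes of these 4 lists passed without either control replicate.

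None of the 23 replication and mitosis genes passed by edgeR, and 0 adjusted over the list alone, with a camera adjusted p of 0.942. Top2a was at 0.69 ± 0.33 and at −0.11 after GC correction, where Mki67 rose (0.69). Of them 9 and 7 rose and 12 and 9 fell without ATRA replicate 1 or 2. None of 6 cyclin-dependent kinase inhibitor genes passed in either fit (0 adjusted over the list alone, or 2 that rose after GC correction), with a camera adjusted p of 0.939 and Cdkn1a at 69.4 ± 4.41 CPM in the controls and 34.7 ± 12.3 with ATRA (log2 fold change −0.15 after GC correction). With ATRA replicate 1 or 2 left out, 3 and 0 rose and 3 and 1 fell uncorrected, and 2 and 3 rose and 0 and 1 fell corrected. Of 15 p53 targets 0 passed, or 2 rose and 4 fell adjusted over the list alone, with a camera adjusted p of 0.942 and Ccng1 at 1.22 and 0.24. After GC correction 3 rose and 2 fell, and without either control replicate 0. Of the p53 targets 7 and 6 rose and 5 and 4 fell without ATRA replicate 1 or 2. In the lists where edgeR called 0 genes, an unadjusted p under 0.05 was held by 10 replication and mitosis genes, 2 kinase inhibitors, 10 p53 targets, 7 hypoxia genes, 6 Nodal pathway genes, 9 liver X receptor targets, 7 trophoblast genes and 3 fibroblast genes. Over all 14256 genes tested, 5941 had such a p, so these counts alone do not set a list apart. In the order of the lists above, DESeq2 called 7, 1, 6, 5, 5, 8, 4 and 3 members, and limma-voom 0, 0, 4, 3, 0, 5, 3 and 2. Over all genes DESeq2 called 4268 of 14183, and limma-voom 1620 of 14256.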

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

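All tests of explanations in this part were chosen after the results were seen.

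Reads that fell in no annotated gene, which the comparisons above do not use, made up 64.7% of the reads in the count tables in ATRA replicate 1 and 66.2% in ATRA replicate 2. Both lie above the control libraries, at 63.4% and 63.9%. This share of reads, which is in unused data, was higher in the treated samples, and with 2 libraries per group an exact permutation test cannot reach a p under 0.05. The strand setting and the annotation of the counting are not stated, and whether they match the library type, which bears on the level of this share in all 4 libraries, was not tested.

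The trend of fold changes with transcript GC content was weighed as a pattern. It was present between the ATRA libraries, which share the treatment: the Spearman rho across genes of GC content and their log2 ratio was −0.78, so a difference in GC bias between libraries may account for that part. Transcript length in place of GC content is argued against by a partial rho of length at fixed GC of 0.0694, against −0.768 for GC at fixed length. Annotated length is no direct measure of broken RNA, so this value does not decide on RNA breakage. The gap in that ratio between the GC deciles with the highest and the lowest content was −2.16, but 2 single libraries give no spread between treated cultures, so a bias and an uneven response to the treatment cannot be told apart. The same holds for ATRA replicate 1 against the controls (−1.71), because every ATRA library is also a treated one.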

How the results depend on the processing

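The GC-corrected settings, alone or with another change, and the tests of leaving out a library within them were chosen after the results were seen; the others were planned.

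The count of changed genes depended on the processing. The direction of single genes was followed in the 72 named genes only. The 54 called ones among them were picked by the uncorrected fit and differed at least 2-fold in it, so a kept sign was likely from the start. Changed genes numbered 161 as reported (103 higher and 58 lower, all at least 2-fold). DESeq2 size factors gave 603 (232 and 371, 603 at least 2-fold), and library size alone 25 (18 and 7, all 25 at least 2-fold), with the median of all genes at −0.11. The DESeq2 test gave 4268 (1615 and 2653, 4078 at least 2-fold), limma-voom 1620 (433 and 1187, 1617 at least 2-fold) and the older quasi-likelihood method 86 (62 and 24, all 86 at least 2-fold). A filter of 5 CPM in 2 libraries gave 84 (59 and 25, all 84 at least 2-fold), and the test against a 2-fold change 30. At an adjusted p under 0.01 edgeR called 0 genes in each direction and 0 at least 2-fold, while 5941 had an unadjusted p under 0.05. The GC correction gave 2312 (1216 and 1096, 1352 at least 2-fold), and with transcript length 2174 (1108 and 1066, 1270 at least 2-fold). Within it, library size alone gave 1470 (780 and 690), and the filter of 5 CPM 861 at least 2-fold. The cause of these differences was not tested, except that a stricter filter or threshold tests or passes fewer genes. A non-robust fit (204) and no count filter (174) stayed within 1.5 times.

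Replicate numbers pair nothing in the labels. With 2 pairs the correlation across genes of the replicate differences was 0.18, or −0.03 after GC correction. So few pairs cannot show whether libraries with the same number share a culture or a batch. With the replicate block edgeR called 4401 genes (1350 and 3051, 4401 at least 2-fold), and with the replicate block and GC correction 2657 (1342 and 1315, 1679 at least 2-fold).

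Leaving out each library in turn gave 125 to 10289 changed genes (51 to 5011 higher, 74 to 5278 lower, 125 to 7284 at least 2-fold), and after GC correction 25 to 6699 (19 to 3566 higher, 6 to 3133 lower, 25 to 2779 at least 2-fold). The lone library is then assumed to vary like the other group. Without control replicate 1 and 2 the count was 125 and 662, and without ATRA replicate 1 and 2 it was 10289 and 7302.

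With an estimated correlation camera passed 0 lists, and 0 after GC correction. The preset correlation passed 13 and 15, and fry 12 and 13. With 4 libraries the version with an estimated correlation could hardly pass any list, so its 0 lists decide nothing. Even HOX groups 1 to 5 went from a camera adjusted p of 1.96e-37 to 0.145. Some lists turned direction, most without passing in either setting, and the cause was not tested. Adjusted p values follow in the order GC correction, with length, with block and GC correction, with an estimated correlation after GC correction, and by fry after it. They were 0.0199, 0.0233, 0.0373, 0.294 and 0.0238 for the RAR and RXR list, 0.440, 0.398, 0.184, 0.769 and 0.280 for the kinase inhibitors, 0.936, 0.976, 0.772, 0.962 and 0.666 for the Wnt targets, and 0.585, 0.585, 0.623, 0.698 and 0.0493 for the fibroblast list. Definitive endoderm turned with GC correction (0.958), with length (0.988) and with an estimated correlation (0.962). The coregulators turned with GC correction (0.958), with block and GC correction (0.902), with an estimated correlation (0.962) and by fry (0.581), and the Nodal list with block and GC correction (0.871). With the filter of 5 CPM the RAR and RXR list (0.942), the kinase inhibitors (0.942), extraembryonic endoderm (0.586) and the fibroblast list (0.979) turned, and with library size alone the p53 targets (0.990). With a library left out, adjusted p ranged from 0.493 to 0.972 for extraembryonic endoderm and from 0.522 to 0.720 for definitive endoderm (both turned without either ATRA replicate), from 0.611 to 0.978 for replication and mitosis (turned without control replicate 2) and from 0.685 to 0.975 for the kinase inhibitors (turned without control replicate 1). The HOX difference lost its call with paralog groups 1 to 4 against 5 to 13 (1.65) and with the filter of 5 CPM (0.58, 11 against 4 genes), and otherwise ranged from 2.41 to 3.65. Klf2 turned to 0.13 after GC correction and 0.16 with length. Genes without a call turned after GC correction, with length, and with block and GC correction: Rara to 0.34, 0.31 and 0.34, Rxra to 0.18, 0.11 and 0.18, Rxrb to 0.0227, 0.00577 and 0.0180, and Top2a to −0.11, −0.16 and −0.11. Sox2 turned to 0.00936 with GC and length correction. Slc2a3 ranged from −0.0161 to 0.39 with a library left out, the lower value without ATRA replicate 1. Sox2 ranged from −0.71 to 0.28 with a library left out, the higher value without ATRA replicate 1. All but Klf2 (53 of the 54 named genes called) kept their sign in every setting. Of 1145 pairs of a named gene and a setting, 960 kept direction and side of the threshold, 99 lost the call, 69 gained it and 17 turned. Of 417 such pairs for lists, 312 kept both, 50 lost, 16 gained and 39 turned. Depth limits what low counts can show, since 3 counts are 0.0968 CPM in the deepest library and 0.271 CPM in the shallowest.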

Other observations

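All genes in this part, and all its tests, were chosen after their values were seen.

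Values of some genes outside the preset lists follow. Emx2, a forebrain and urogenital homeobox gene, went from 0.619 ± 0.0560 to 7.90 ± 1.67 CPM (log2 fold change 3.64 ± 0.42, or 4.06 after GC correction), and Olig3, a dorsal neural tube gene, was at 3.71 (4.14). The endothelin receptor gene Ednrb and the receptor phosphatase gene Ptprz1 also rose, the latter by 3.80 (3.11 after GC correction). Greb1l rose from 14.9 ± 0.808 to 217 ± 56.2 CPM, and the arginase gene Arg1 by 4.73 (4.45). The metallothionein gene Mt1 fell from 80.2 ± 27.5 to 5.96 ± 3.47 CPM, a log2 fold change of −3.73 (−3.26). Mt2 was at −3.57 with an edgeR adjusted p of 0.0532 and passed after GC correction (−2.56, edgeR adjusted p = 0.0104). Bmp4 fell, at −2.87 and −2.44, and so did the kinase gene Pim2, at −3.16 and −2.17.

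The 6 Zscan4 genes, whose GC content is 42.3% to 44.4%, were higher with ATRA. A GC bias of the size fitted over all genes, as the whole cause, is argued against by their median GC-corrected log2 fold change of 1.58. The median SE was 0.14, but the copies are not independent and the correction itself lowered the spread between libraries. A bias particular to these copies was not tested. A biological cause may remain, but 24 h of culture and ATRA vary together. Zscan4c and Zscan4f, the members called without GC correction, lost their calls when either control library was left out.

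Ribosomal protein genes (76 tested) had a median log2 fold change of −0.97, with 0 called, and of −0.57 after GC correction, where 23 fell and 1 rose. Their transcripts are short, with a median length of 942 bases against 3105 over all genes. Once length was corrected too, the median was −0.39 (SE 0.11 over genes, which are not independent) and 18 fell. This argues against length bias as the whole cause only as far as the longest annotated transcript measures length. Between the ATRA libraries the median difference was −0.44 after GC correction and −0.33 with length, but single libraries give no spread between treated cultures, so a library effect and the treatment cannot be told apart. Against the control mean the medians were −0.34 and −0.90, or −0.21 and −0.60 with length.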
